A study of Homo sapiens with 4 samples.

How the data were processed

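RNA sequencing was done on RUES2 cells, an established human embryonic stem cell line, grown as disc-shaped colonies of 500 µm diameter on micropatterned coverslips. Per the labels' protocols, the cells were kept in medium conditioned by mouse embryonic fibroblasts with 20 ng/ml basic FGF, and BMP4, a ligand of the TGF-beta superfamily, was given at 50 ng/ml. Total RNA was taken with Trizol and RNeasy columns at 0, 4, 12 and 24 h, and libraries were made with the Illumina TruSeq RNA kit in its second version, per the labels' protocols. That kit does not mark strand, so reads of a gene and of an overlapping antisense RNA cannot be told apart. There was 1 library per time point, 4 in all, and there were no replicates.

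The deposited values are a signal, gene-wise read counts that the authors divided by 1 DESeq2 size factor per library. Per the submitters' processing notes, reads were aligned with STAR, counted with featureCounts and normalized with DESeq2. Tool versions, counting options, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The table has 57445 versioned Ensembl gene identifiers and 1 column per library.

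The reads behind the values were recovered. In each column every value was a whole multiple of 1 step, which was 1.01 at 0 h, 1.07 at 4 h, 0.954 at 12 h and 0.957 at 24 h. With these steps 100% of the values above 0 came within 0.01 of a whole number of reads in all 4 libraries. The recovered totals were 125659015 reads at 0 h, 119913481 at 4 h, 129510085 at 12 h and 135752899 at 24 h. Reads were found on 29326, 29083, 29744 and 29682 genes, in order of time. The 10 most abundant genes took 5.78% to 6.09% of the reads, and genes of the mitochondrial genome 4.73% to 5.03%.

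Among genes with fewer than 20 reads, 76.2%, 75.9%, 74.9% and 76.9% of the read numbers were even, in order of time, against 50% if even and odd were equally frequent. Among genes with more than 100 reads the even share was 53.2% to 53.8%. The intervals below therefore count 2 reads as 1 read pair, and the floor is 3 read pairs, or 6 reads. Intervals are 95% intervals. The interval of a ratio is the exact conditional binomial one, taken without a pseudocount, and the interval of a level is the exact Poisson one. Amplified reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. They say nothing about variation between cultures.

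Ratios were computed as log2 of the value plus 1 over the reference value plus 1, and folds are on that scale, which understates ratios of genes with low values. A gene was measured if its mean normalized count over the 4 libraries was at least 50, which 17512 genes met. A gene was called higher or lower if the ratio was at least 2-fold. The comparisons were 4, 12 and 24 h against 0 h, 12 h against 4 h and 24 h against 12 h. No test between times was possible with 1 library per time, and a count model on the recovered reads could not be fitted without an assumed spread, so no p-value is given and no difference has a replicate check. For a gene with 0 reads at 0 h or at the later time the fold is given as a bound against the floor.

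Gene symbols came from the current reference name table for 39410 identifiers and from GENCODE release 29 for 816 more. The other 17219 identifiers stayed without a symbol, 1225 of them among the measured genes. The reference annotation was used for names and for which genes neighbour each other. Before the data were examined, 40 gene lists with 726 entries were fixed. Of these entries 718 matched an identifier and 608 met the expression minimum, and the rest were not analysed here. A gene can stand in several lists. For each list and time, the median log2 ratio was placed among the medians of 10000 random lists with the same number of genes in each of 20 bins of mean expression. The percentile is a description of these libraries and does not mean that a whole list shifted. At 4 h the binomial interval of the median held 0 for several lists placed high, such as canonical WNT targets (-0.48 to 0.62) and HOX and CDX genes (-0.81 to 3.23). It also held 0 for amnion genes (-0.02 to 4.47) and neural crest and surface ectoderm genes (-0.26 to 4.47). It lay above 0 for BMP-SMAD targets (1.91 to 3.58) and trophectoderm and trophoblast genes (0.09 to 1.88). The same was true of lists with small medians, such as cytosolic ribosomal protein genes (0.06 to 0.10) and G2 and mitosis genes (0.05 to 0.18). Of 120 such placements, 68 fell outside the central 95% of the random lists, where 6 would by chance if the lists were independent draws.

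The rule for which genes are named was set with the lists, and it picks genes by their values except for the fixed ones. It names the 10 measured genes with the largest and the 10 with the smallest ratio at 4, 12 and 24 h against 0 h, up to 4 members of each list and time with the largest ratios in size among those past the 2-fold rule, and 22 genes of the BMP, NODAL and WNT pathways, of cell states and GAPDH, whatever their ratio. Results for some genes that this rule selects are not reported. Other genes are named only where the text says that they were chosen after their values were seen.

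The code was tested on simulated libraries drawn from the real means and size factors for 4 h against 0 h, with 200 genes changed by known folds. Over 17362 simulated genes that met the minimum, the 2-fold rule called 0 of 50 genes changed 1.5-fold, 24 of 50 changed exactly 2-fold, 48 of 50 changed 4-fold and 47 of 50 changed 8-fold. The genes missed at 4-fold and 8-fold, 2 and 3, had dropped below the expression minimum. Of 17169 unchanged genes, 16 passed the rule. The 95% intervals held the true ratio for 95.7% of the genes, and 10 of 200 unchanged lists of 15 genes fell outside the central 95% of random lists. The simulation held counting noise only, and its lists were drawn at random from unchanged genes. It therefore checks the code and does not give the rate of false calls between cultures.

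Alternatives were pseudocounts of 0.5 and 10, minimum means of 10, 200 and none, total-count, upper-quartile and edgeR TMM scaling, centring on the median gene, folds of 1.5 and 4, and counting intervals wholly beyond 2-fold. Chosen after seeing the data were a rule that the counting interval also excludes 1, a count over protein-coding genes, and intervals that take each read as 1 count. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.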

Results

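Gene expression was measured by RNA sequencing in micropatterned colonies of RUES2 human embryonic stem cells before BMP4 and at 4, 12 and 24 h of BMP4, with 1 library per time and no replicates. Such colonies form rings of different cell states when BMP4 is given, and the series title names secreted inhibitors and sensing of the colony edge as its subject. The time course asks which inhibitors, ligands, receptors and cell state genes are expressed as the colony responds. The libraries held between 119913481 and 135752899 reads. Values are DESeq2-normalized counts from whole colonies, so they do not show which cells express a gene. Every difference below is between individual libraries and has no replicate check, and bracketed intervals cover counting error only.

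The first comparison, 4 h against 0 h, asks which genes differed early after BMP4. There was no culture without BMP4 at the same times, so effects of BMP4 and of time in culture are not separated, nor direct from secondary targets. Of 17512 measured genes, 494 were at least 2-fold higher and 200 at least 2-fold lower, and 159 and 21 passed 4-fold. With the 95% counting interval wholly beyond 2-fold there were 269 higher and 58 lower genes. With no expression minimum the balance turned, to 3652 higher and 3880 lower. Of the lists, BMP-SMAD targets had the highest median: 14 of 18 BMP-SMAD target genes were higher and 0 lower, with a median log2 ratio of 2.60 at percentile 100 of random lists. ID1, an inhibitor of basic helix-loop-helix factors, was 5.61-fold higher (5.42 to 5.81), and ID3 was 4.64-fold higher (4.53 to 4.77). The pseudoreceptor gene BAMBI was 7.65-fold higher (7.31 to 8), and the transcription factor genes MSX2 and GATA2 were 31.9-fold and 31.6-fold higher. SMAD6, which encodes an inhibitory SMAD, was 18.2-fold higher (14.5 to 23.3) and SMAD9 12.0-fold higher (9.15 to 16.3).

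Secreted inhibitors were among the early genes. Of 19 measured inhibitors of BMP and activin, 4 were higher at 4 h and 0 lower (median log2 ratio 0.34, percentile 100). The binomial interval of that median, -0.12 to 0.87, holds 0. NOG (ENSG00000183691.4), which encodes the BMP antagonist noggin, went from 12.1 to 483 normalized counts, 37.0-fold higher (18.1 to 110). GREM1 (ENSG00000166923.6) was 4.25-fold higher (3.97 to 4.55) and SOSTDC1 2.47-fold higher (1.51 to 4.28). CHRD, which encodes chordin, stood at 165 and 223 counts, a ratio of 1.35 (1 to 1.83), CER1 at 2069 and 3444 counts, a ratio of 1.66 (1.54 to 1.80), and the activin antagonist FST at 3487 and 3205 counts. Among 11 secreted WNT inhibitors 2 were higher and 0 lower (median 0.15, percentile 98.8). NOTUM (ENSG00000185269.7), which encodes an enzyme that inactivates WNT ligands, was 59.4-fold higher (34.5 to 125). DKK1 was 75 and 82 counts, a ratio of 1.09 whose interval of 0.678 to 1.77 holds 1.

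Among ligands and receptors at 4 h, some genes were higher and others lower. Of 11 WNT ligands 3 were higher and 1 lower (median 0.43, percentile 99.9). WNT3 was 3.46-fold higher (3.14 to 3.83) and WNT3A 11.1-fold higher (6.09 to 24.9), while WNT5A was 2.07-fold lower (1.72 to 2.48). The third higher WNT ligand, WNT6, had 0 and 2 reads, under the floor at both times; with values under the floor set to it, 2 ligands were higher and the median was 0.20. Of 10 BMP ligands 2 were higher, BMP7 by 3.75-fold (3.37 to 4.19) and GDF7, and 0 lower (median -0.16, percentile 8.15). Of 15 BMP and activin receptors and co-receptors, BMPR2 was 2.06-fold higher (1.94 to 2.19) and RGMA 2.28-fold lower (2.09 to 2.49), with a median of 0.00 at percentile 50.6. BMPR1A stood at 16118 and 28406 counts, a ratio of 1.76 (1.71 to 1.81), and ACVR2B at 2086 and 1765. SMAD9 was the 1 higher gene of 12 SMAD transducers (median 0.13, percentile 99.5). Of 14 NODAL pathway genes 2 were higher, INHBB by 6.97-fold (4.63 to 11.3) and the convertase gene FURIN by 2.03-fold (1.96 to 2.10), which fell short of 2-fold with total-count scaling, and NODAL itself (ENSG00000156574.5) stood at 2426 and 2515 counts (list median 0.11, percentile 96.6).

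Few WNT and FGF-ERK target genes passed 2-fold at 4 h. Of 15 canonical WNT target genes 1 was higher, NOTUM, and 2 lower, AXIN2 by 2.78-fold (2.52 to 3.06) and the receptor gene FZD7 by 2.37-fold (2.31 to 2.43), although the list median of 0.37 lay at percentile 100. Of 16 FGF-ERK target genes 0 were higher and 1 lower, DUSP4 by 2.07-fold (1.68 to 2.57), with a median of -0.18 at percentile 0.07. Of 12 FGF ligands, FGF4, FGF9 and FGF18 were higher and FGF16 lower (median -0.08, percentile 21.4; 0.01 with values under the floor set to it). Of 15 NOTCH pathway genes, HEY1 by 9.62-fold and HES1 were higher and DLL1 and HEY2 lower (median -0.13, percentile 2.15).

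Cell state genes at 4 h already divided. Of 15 trophectoderm and trophoblast genes 8 were higher (median 1.14, percentile 100), led by TFAP2A at 85.2-fold (55.0 to 140) and GATA3 at 22.2-fold (18.8 to 26.6). Of 13 amnion genes 7 were higher (median 1.65, percentile 100) and of 14 neural crest and surface ectoderm genes 8 were higher and FOXD3 lower (median 1.38, percentile 100). GRHL3, an epidermal transcription factor gene, was 10.1-fold higher (9.02 to 11.3). These lists share members: 13 of the 15 trophectoderm genes, 9 of the 13 amnion genes and 7 of the 14 neural crest and surface ectoderm genes stand in another list. Among the shared ones, GATA3, GATA2 and MSX2 are also BMP-SMAD target genes reported above. The higher genes of these lists are therefore not separate from the BMP-SMAD result. VGLL1 and WNT6, with 0 and 2 reads each, pass the rule by the pseudocount alone; with values under the floor set to it, 7 trophectoderm and 6 amnion genes were higher, with medians of 0.48 and 0.74. Of 23 pluripotency genes 0 were higher and 3 lower (median -0.14, percentile 0), among them FOXD3 by 4.45-fold (3.80 to 5.22) and PRDM14 by 2.55-fold (2.45 to 2.66). Of 15 neural ectoderm genes SIX3 was higher and SOX3, SOX21 and OTX2 lower (median -0.42, percentile 0), SOX3 by 3.36-fold (2.87 to 3.96).

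Most primitive streak genes did not pass 2-fold at 4 h. Of 19 such genes 5 were higher and 1 lower (median 0.40, percentile 99.98), the higher ones including WNT3A, EVX1, FGF4 and HAND1, which was 3.67-fold higher (2.78 to 4.97). TBXT (ENSG00000164458.5), which encodes brachyury and was the lower gene, had 28.2 and 10.7 counts; its interval of 0.107 to 1.12 holds 1, so a difference was not detectable at this depth. Of 11 definitive endoderm genes 4 were higher and 0 lower (median 0.69, percentile 100), HHEX by 11.6-fold (8.33 to 16.5), PRDM1 by 2.52-fold, GATA4 by 2.19-fold and FOXQ1, while SOX17 stood at 24.2 and 23.6 counts. Of 12 primordial germ cell genes 3 were higher, NANOS3, PRDM1 and TFAP2C (median 0.08, percentile 87.4). Of 7 measured HOX and CDX genes 4 were higher (median 1.87, percentile 100; 1.32 with the floor), among them HOXB9 and HOXD1 at 9.36-fold and 8.65-fold.

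By the largest ratios at 4 h, the higher genes were LINC02593, TFAP2A, SAMD11, NOTUM, GATA3-AS1, GATA5, DMRTA2, UTS2R, CDKN2C and BHLHE22. LINC02593, a non-coding RNA gene next to SAMD11, stood at 1.01 and 855 counts, with an interval of 75.8 to 16813, and SAMD11 was 78.5-fold higher (52.1 to 124). GATA3-AS1, which overlaps GATA3 on the other strand and cannot be told apart from it without strand, had 0 reads at 0 h and was at least 9.42-fold higher. GATA5 was 52.9-fold higher (27.2 to 142). The lower genes were MOBP, GABRA4, PRICKLE1, MUC15, PROX1, MSC, GBX2, LRAT, HES3 and APLN. PRICKLE1, of the planar cell polarity pathway, was 7.53-fold lower (6.77 to 8.41), LRAT, which encodes a retinol-esterifying enzyme, 5.64-fold lower (5.03 to 6.32), and APLN 5.27-fold lower (3.85 to 7.52). MOBP, GABRA4 and MUC15 had 0 reads at 4 h against 14.1, 8.06 and 6.04 counts at 0 h, and the upper interval bounds of their ratios were 0.740, 1.62 and 2.58, so for GABRA4 and MUC15 a difference was not detectable at this depth.

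**Figure D1:**
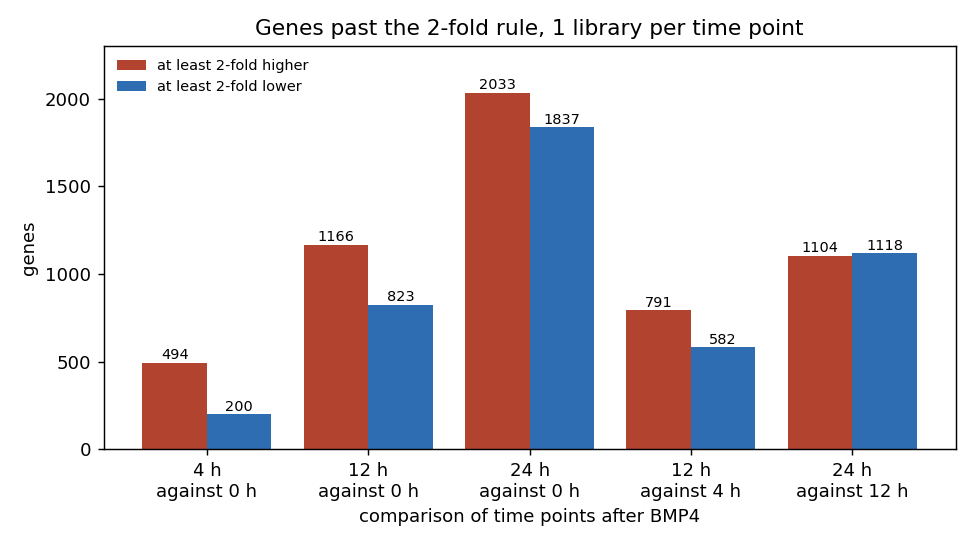
Number of genes (vertical axis) at least 2-fold higher (red bars) or lower (blue bars) in each comparison of time points (horizontal axis), among 17512 measured genes with 1 library per time. The counts against 0 h were 494 and 200 at 4 h, 1166 and 823 at 12 h, and 2033 and 1837 at 24 h.

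The comparison of 12 h with 0 h gave 1166 higher and 823 lower genes, 383 and 153 of them past 4-fold. BMP-SMAD targets were still higher, 16 of 18 with 0 lower (median 3.88, percentile 100). MSX2 was 159-fold higher (121 to 220), GATA2 63.0-fold (51.1 to 79.8), SMAD6 57.6-fold (45.9 to 73.2), ID1 7.96-fold (7.70 to 8.23), BAMBI 8.41-fold (8.05 to 8.79) and ID3 3.05-fold (2.97 to 3.14). Among BMP ligand genes, BMP4 was 16.7-fold higher (15.2 to 18.4) and BMP7 13.9-fold higher (12.6 to 15.3), while BMP2 was 3-fold lower (2.53 to 3.57). With GDF7 this made 3 of 10 BMP ligands higher and 1 lower (median -0.32, percentile 3.24; 2.10 with a minimum mean of 200).

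Secreted inhibitors parted at 12 h. Of 19 BMP and activin inhibitors 5 were higher and 3 lower (median 0.30, percentile 99.1). NOG reached 2305 counts, 176-fold over 0 h (87.4 to 521), SOSTDC1 was 10-fold higher (6.65 to 16.4) and FST 2.02-fold (1.91 to 2.14), which fell short of 2-fold with upper-quartile scaling. LEFTY1 (ENSG00000243709.1), which encodes a NODAL antagonist, went from 3368 to 94.4 counts, 35.3-fold lower (26.7 to 47.8). CER1, an antagonist of NODAL and BMP that also stands in the list of secreted WNT inhibitors, was 3.13-fold lower (2.77 to 3.55). LEFTY1 and LEFTY2 are close paralogs, and how reads they share were counted is not given in the sources used here. CHRD and GREM1 stood at 241 and 3557 counts, ratios of 1.46 (1.10 to 1.96) and 1.70 (1.57 to 1.83). Of 11 secreted WNT inhibitors 3 were higher and 3 lower (median -0.12, percentile 15.7): NOTUM was 127-fold higher (74.2 to 267) and SFRP1 3.10-fold lower (3.03 to 3.18). Of 14 NODAL pathway genes 4 were higher and 3 lower (median 0.06, percentile 70.0); INHBA was 4.14-fold lower (3.45 to 5.02) and FURIN 2.68-fold higher (2.59 to 2.76). NODAL stood at 2507 counts, a ratio of 1.03 (0.955 to 1.12).

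**Figure D2:**
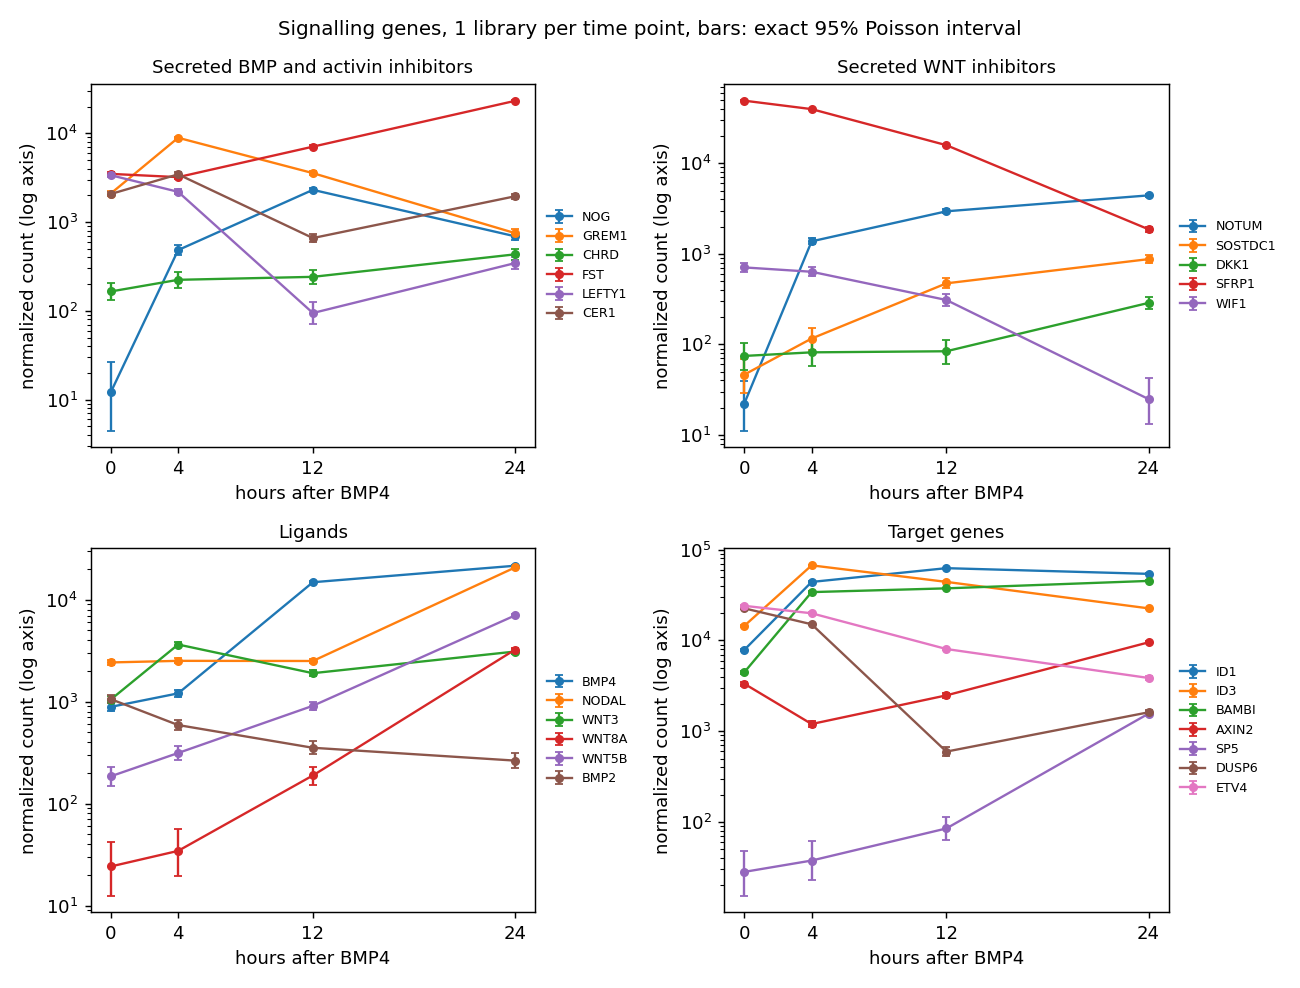
Normalized counts (vertical log axes) against hours after BMP4 (horizontal axes) for secreted inhibitors, ligands and target genes, 1 library per time, with bars for the exact 95% Poisson interval of the read pairs. NOG was highest at 12 h (2305) and GREM1 at 4 h (8896), NODAL stood between 2426 and 2515 until 12 h and at 20727 at 24 h, and DUSP6 was lowest at 12 h (596).

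FGF-ERK target genes had the lowest list median at 12 h: 10 of 16 were lower and 0 higher, with a median of -1.23 (-1.58 to -0.76, binomial interval of the median) at percentile 0. DUSP6, which encodes an ERK phosphatase, went from 22591 to 596 counts, 37.8-fold lower (33.8 to 42.5). DUSP5 was 3.74-fold lower (3.44 to 4.08), FOSL1 3.25-fold (2.84 to 3.72) and the ETS factor gene ETV4 2.99-fold (2.89 to 3.10). Immediate early genes went the same way in part, with 5 of 14 lower and KLF4 higher (median -0.67, percentile 0.02), MYC, EGR2 and NR4A1 being lower; 4 of the 14 stand in another list. Of 12 FGF ligands 4 were higher and 3 lower (median 0.02, percentile 50.6), FGF16 being 40.4-fold lower (13.7 to 424). Canonical WNT targets were 6 higher and 2 lower of 15 (median 0.25, percentile 97.0). The binomial interval of that median, -0.43 to 1.70, holds 0. The higher ones included NOTUM by 127-fold, BMP4 by 16.7-fold and RNF43 by 3.59-fold (2.68 to 4.96), and FZD7 was 4.89-fold lower (4.75 to 5.04). BMP4 also stands in the list of BMP-SMAD targets. Of 11 WNT ligands 4 were higher and 2 lower (median 0.67, percentile 99.7), WNT8A by 7.54-fold (4.28 to 15.6) and WNT5B by 4.90-fold (3.93 to 6.22), and WNT3 stood at 1903 counts, a ratio of 1.81 (1.63 to 2.02); with values under the floor set to it 3 were higher and the median was -0.06.

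Among cell state genes at 12 h, pluripotency genes were 2 higher and 6 lower of 23 (median -0.38, percentile 0). PRDM14 was 8.17-fold lower (7.69 to 8.70), FOXD3 6.07-fold (5.13 to 7.23), USP44 4.34-fold (4.2 to 4.48) and NANOG 2.05-fold (1.97 to 2.13), while SOX2 stood at 25279 and 23208 counts. Trophectoderm genes were 8 higher and 1 lower of 15 (median 1.49, percentile 100; 7 and 0 with the floor, median 0.92), amnion genes 9 and 1 of 13 (median 3.07, percentile 100; 8 and 1 with the floor) and neural crest and surface ectoderm genes 9 and 2 of 14 (median 2.81, percentile 100; 9 and 1 with the floor). TFAP2A was 370-fold higher (239 to 605), GATA3 42.0-fold (35.6 to 50.2), CDX2 (ENSG00000165556.9) 21.9-fold (11.9 to 51.1) and ISL1 21.3-fold (15.5 to 30.9). Streak and mesoderm genes were 7 higher and 2 lower of 19 (median 0.42, percentile 99.8); HAND1 was 19.7-fold higher (15.4 to 26.0), and TBXT stood at 38.2 counts with an interval of 0.650 to 2.90. Endoderm genes were 2 higher, HHEX and KIT, and 1 lower, CER1, of 11 (median 0.39, percentile 97.3), and SOX17 stood at 43.9 counts (interval of the ratio 0.867 to 4.00). Primordial germ cell genes were 5 higher and 1 lower of 12 (median 0.61, percentile 99.9) and HOX and CDX genes 6 and 0 of 7 (median 2.25, percentile 100). Neural ectoderm genes were 1 higher and 4 lower of 15 (median -0.41, percentile 0.19), HESX1 by 12.5-fold lower (9.69 to 16.4) and OTX2 by 5.25-fold lower (4.87 to 5.67).

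By the largest ratios at 12 h, the higher genes included LINC02593, EN1, TFAP2A, GRIN3A, GATA3-AS1, NOG, SAMD11, MSX2 and GATA5. EN1 had 0 reads at 0 h and 409 counts at 12 h, at least 67.7-fold higher. The lower genes with symbols were FGF16, DUSP6, LEFTY1, LRAT, PTX3, HTR1A, SLA, APLN and D21S2088E, together with 1 identifier without a symbol. LRAT was 28.2-fold lower (22.6 to 36.0) and PTX3, which encodes a pentraxin, 22.6-fold lower (12.3 to 52.8).

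The comparison of 24 h with 0 h had 2033 higher and 1837 lower genes, 809 and 605 past 4-fold. With upper-quartile scaling the balance turned, to 1749 higher and 2160 lower. BMP-SMAD targets were 15 of 18 higher and 0 lower (median 4.32, percentile 100). MSX2 was 298-fold higher (225 to 411), ID1 6.89-fold (6.66 to 7.12) and BAMBI 10.2-fold (9.72 to 10.6), and ID3 had a ratio of 1.56 (1.52 to 1.61). BMP4 was 24.2-fold higher (22.0 to 26.7), BMP7 15.7-fold (14.2 to 17.3) and BMP2 4.00-fold lower (3.32 to 4.87), and BMP ligands were 3 higher and 2 lower of 10 (median -0.21, percentile 19.2; 3 lower with the floor, and median 1.85 with a minimum mean of 200). Receptors were 4 higher and 2 lower of 15 (median 0.38, percentile 97.1): BMPR2 was 3.74-fold higher (3.53 to 3.96), ACVR1 3.38-fold (3.19 to 3.59), BMPR1A 2.07-fold (2.01 to 2.12) and ENG was the fourth, while ACVR2B had a ratio of 1.3 (1.20 to 1.41). BMPR1A fell short of 2-fold with upper-quartile scaling, which lowered the median of all genes at 24 h to -0.11. SMAD transducers were 2 higher and 0 lower of 12 (median 0.41, percentile 99.3), SMAD9 and TGIF2.

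Inhibitors, NODAL and WNT genes were far apart at 24 h. Of 19 BMP and activin inhibitors 6 were higher and 4 lower (median 0.00, percentile 46.5). NOG was 52.9-fold higher (26.0 to 157), SOSTDC1 18.5-fold (12.4 to 30.1), FST 6.64-fold (6.32 to 6.99) and CHRD 2.61-fold (2.03 to 3.41). GREM1 was 2.79-fold lower (2.48 to 3.14) and LEFTY1 9.75-fold lower (8.38 to 11.5), and CER1 was 1949 counts, a ratio of 0.942 (0.863 to 1.03). Secreted WNT inhibitors were 4 higher and 4 lower of 11 (median -0.31, percentile 7.21): NOTUM 191-fold (111 to 400) and DKK1 3.82-fold (2.67 to 5.68) higher, WIF1 27.4-fold (16.4 to 54.0) and SFRP1 26.3-fold (24.7 to 28.1) lower. NODAL was 8.54-fold higher (8.05 to 9.07) at 20727 counts. NODAL pathway genes as a list were 3 higher and 5 lower of 14 (median -0.08, percentile 25.5; 0.21 with a minimum mean of 10 or 200 or none), INHBA being 20.5-fold lower (14.1 to 30.9).

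WNT ligands were 5 higher and 0 lower of 11 at 24 h (median 0.90, percentile 99.6). WNT8A was 129-fold higher (76.5 to 260), WNT5B 37.6-fold (30.8 to 47.1), WNT3A 5.84-fold (3.10 to 13.3) and WNT3 2.96-fold (2.68 to 3.27), and WNT6, with 0 reads at 0 h, was at least 61.9-fold higher. Canonical WNT targets were 11 higher and 1 lower of 15 (median 2.01, percentile 100), RNF43 by 94.7-fold (73.3 to 127) and SP5 by 53.5-fold (32.8 to 102). FGF-ERK targets were 0 higher and 12 lower of 16 (median -1.43, percentile 0): DUSP6 by 14.0-fold (13.0 to 15), FOSL1 by 9.28-fold (7.58 to 11.6) and ETV4 by 6.23-fold (5.95 to 6.54). FGF ligands were 6 higher and 3 lower of 12 (median 0.66, percentile 99.2), FGF7 and FGF9 among the higher. NOTCH pathway genes were 3 higher and 4 lower of 15 (median 0.37, percentile 96.4), against 3 and 2 at 12 h (median 0.03, percentile 58.2).

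Lists for several lineages had more higher than lower genes at 24 h in the same RNA, but their counts are not independent. Of the streak and mesoderm genes 12 of 19 stand in another list, of trophectoderm genes 13 of 15, of amnion genes 9 of 13 and of primordial germ cell genes 6 of 12. Of BMP-SMAD targets 9 of 18 do, GATA3 among them. Streak and mesoderm genes were 14 higher and 0 lower of 19 (median 2.56, percentile 100): HAND1 was 325-fold higher (256 to 426), TBXT 83.2-fold (51.1 to 158) at 2427 counts and EOMES 9.43-fold (8.13 to 11). Endoderm genes were 7 higher and 0 lower of 11 (median 1.5, percentile 99.98), and SOX17 was 7.49-fold higher (4.25 to 15.5) at 188 counts. Trophectoderm genes were 12 higher and 1 lower of 15 (median 4.75, percentile 100), amnion genes 10 and 0 of 13 (median 3.76, percentile 100), primordial germ cell genes 8 and 1 of 12 (median 2.18, percentile 100), neural crest and surface ectoderm genes 11 and 1 of 14 (median 5.35, percentile 100) and HOX and CDX genes 7 and 0 of 7 (median 5.14, percentile 100). TFAP2A was 639-fold higher (413 to 1046), CDX2 506-fold (281 to 1169), ISL1 209-fold (154 to 301), GATA3 67.2-fold (57.0 to 80.4) and the keratin gene KRT7 19.3-fold (17.3 to 21.7). The HOX gene HOXB6 was 40.7-fold higher (20.0 to 121).

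Pluripotency genes at 24 h were 1 higher, KLF4, and 10 lower of 23 (median -0.94, percentile 0). FOXD3 was 47.2-fold lower (31.2 to 79.6), USP44 23.1-fold (21.5 to 24.8), PRDM14 12.9-fold (12.0 to 13.9), SOX2 (ENSG00000181449.2) 5.54-fold (5.30 to 5.79) and NANOG 2.39-fold (2.29 to 2.49). POU5F1, the OCT4 gene, stood at 185884, 206536, 212225 and 221122 counts over the course, a ratio of 1.19 (1.18 to 1.20) at 24 h. POU5F1 and NANOG share sequence with pseudogene copies, and how shared reads were counted is not given in the sources used here. Neural ectoderm genes were 2 higher and 8 lower of 15 (median -1.01, percentile 0): HESX1 by 39.9-fold (25.7 to 65.7), POU3F1 by 24.0-fold (16.8 to 36.7), PAX6 by 8-fold (3.50 to 28.6) and OTX2 by 6.87-fold (6.32 to 7.49).

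**Figure D3:**
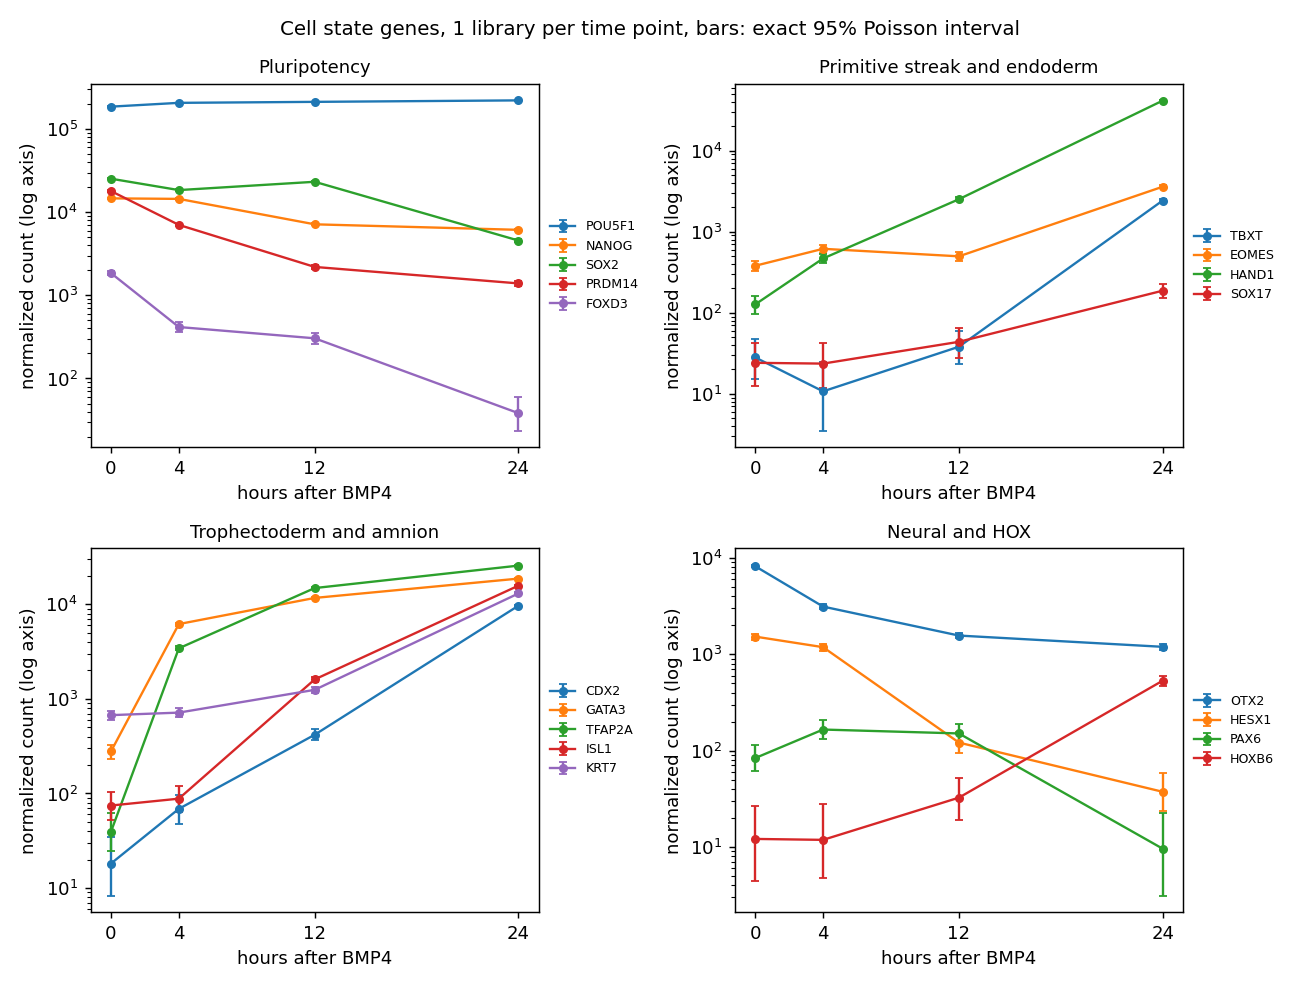
Normalized counts (vertical log axes) against hours after BMP4 (horizontal axes) for genes of pluripotency, primitive streak and endoderm, trophectoderm and amnion, and neural and HOX genes, 1 library per time, with bars for the exact 95% Poisson interval of the read pairs. GATA3 and TFAP2A stood apart from 0 h at 4 h, TBXT only at 24 h (2427), and POU5F1 stayed between 185884 and 221122.

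More adhesion, matrix and cytoskeleton genes passed 2-fold at 24 h than at 4 or 12 h, as was true of all measured genes. The placement of the list medians did not always follow. Extracellular matrix genes lay at percentile 0 at 4 and 12 h and at 7.40 at 24 h. Keratin and cytoskeleton genes lay at 0.53 at 12 h and 3.69 at 24 h. Medians of the junction, EMT and YAP-TEAD lists were placed furthest out at 24 h. Of 23 epithelial junction and polarity genes 0, 2 and 5 were higher at 4, 12 and 24 h and 0 lower (medians -0.07, 0.05 and 0.47, percentiles 0.55, 89.8 and 99.98). The claudin genes CLDN10 and CLDN4 were 88.1-fold (83.0 to 93.6) and 10.1-fold (9.42 to 10.8) higher at 24 h, TJP3 8.37-fold (7.5 to 9.37) and CDH1, the E-cadherin gene, 3.42-fold (3.37 to 3.47). Of 14 EMT and mesenchymal genes 0, 3 and 3 were higher and 0, 1 and 3 lower (medians -0.04, -0.03 and 0.15, percentiles 18.1, 42.0 and 85.4): at 24 h FN1, the fibronectin gene, was 22.8-fold higher (22.3 to 23.2), VIM 9.90-fold lower (9.59 to 10.2) and CDH2 7.34-fold lower (6.99 to 7.72). Of 21 extracellular matrix genes 0, 1 and 3 were higher and 0, 1 and 8 lower (medians -0.17, -0.32 and -0.18, percentiles 0, 0 and 7.40), COL4A5 and COL4A6 being higher and COL1A1 and LAMA3 lower at 24 h. Of 18 simple epithelium keratin and cytoskeleton genes 0, 1 and 4 were higher and 0, 1 and 5 lower (medians 0.02, -0.23 and -0.25, percentiles 38.7, 0.53 and 3.69; 0 higher at 12 h with the floor). Of 16 YAP-TEAD target genes 2, 4 and 7 were higher and 0, 0 and 3 lower (medians -0.06, -0.18 and 0.81, percentiles 5.88, 2.52 and 100; 1 and 3 higher at 4 and 12 h with values under the floor set to it), ANKRD1 and TEAD3 among the higher at 24 h.

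Lists for other cell types showed no common direction towards them. Of 11 fibroblast genes 0, 2 and 2 were higher and 0, 1 and 2 lower (medians -0.12, 0.05 and 0.18, percentiles 2.79, 67.4 and 82.6): THY1 was lower and POSTN higher at 12 and 24 h. Of 7 endothelial and blood genes 1, 1 and 0 were higher and 0, 2 and 4 lower (medians -0.24, -0.59 and -1.39, percentiles 1.85, 0.31 and 0.06), the lower ones at 24 h being ERG, TIE1, TEK and FLT1. At 4 h the immediate early list had 0 higher and FOSB lower of 14 (median -0.10, percentile 10.4), and at 24 h 2 higher and 5 lower (median -0.52, percentile 0.81).

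Of 18 heat shock and unfolded protein genes 0, 2 and 1 were higher and 0, 1 and 1 lower (medians 0.05, 0.09 and 0.23, percentiles 80.0, 95.3 and 97.8), with TRIB3 lower and ASNS higher at 12 and 24 h. Of 16 p53 and apoptosis genes 0, 1 and 1 were higher and 0, 1 and 2 lower (medians -0.02, -0.30 and -0.16, percentiles 29.8, 0.08 and 8.5). Of 17 hypoxia and glycolysis genes 1, 1 and 3 were higher and 0, 4 and 5 lower (medians 0.01, -0.19 and -0.52, percentiles 36.9, 1.72 and 0.04), SLC2A1 and HK2 being lower at 12 h and SLC2A3 and NDRG1 higher at 24 h. Of 18 cholesterol synthesis genes 0, 0 and 2 were higher and 0, 1 and 0 lower (medians -0.05, -0.11 and -0.20, percentiles 2.55, 11.6 and 6.44). None of 19 G2 and mitosis genes passed 2-fold at any time (medians 0.11, 0.28 and 0.23, percentiles 99.97, 100 and 99.4), and of 19 DNA replication genes CCNE2 was lower at 24 h (medians 0.04, -0.11 and -0.30, percentiles 64.9, 10.3 and 0.83). Of 12 histone genes 0, 3 and 3 were higher, H1-2, H2AC6 and H2BC5 (medians 0.05, 0.69 and 0.56, percentiles 79.7, 99.97 and 99.05), and H1-2 at 12 h fell short of 2-fold with upper-quartile scaling. Of 13 imprinted genes and chromatin regulators 0, 3 and 4 were higher and 0, 1 and 1 lower (medians -0.03, -0.29 and 0.29, percentiles 13.7, 0.49 and 97.0), with TET2 and DNMT3L higher and DNMT3B 3.12-fold lower (3.08 to 3.15) at 24 h.

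None of 13 mitochondrial-genome genes (medians 0.07, 0.06 and 0.22, percentiles 82.7, 96.7 and 99.3) or 26 cytosolic ribosomal protein genes (medians 0.09, 0.00 and 0.00, percentiles 98.9, 87.6 and 82.4) passed 2-fold. Of 16 reference genes TFRC was lower at 24 h (medians 0.08, -0.01 and -0.12, percentiles 94.5, 67.2 and 22.6), and GAPDH stood at 584754, 613895, 567916 and 524371 counts. SMAD transducers at 12 h were 1 higher, SMAD9, and 1 lower, TGIF1, of 12 (median 0.21, percentile 98.9), and receptors 1 higher, BMPR2 by 2.61-fold (2.46 to 2.76), and 1 lower, TGFBR2 by 3.04-fold (2.70 to 3.45), of 15 (median -0.05, percentile 28.1). The median over all measured genes was 0.00 at 4 and 12 h and 0.01 at 24 h.

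**Figure D4:**
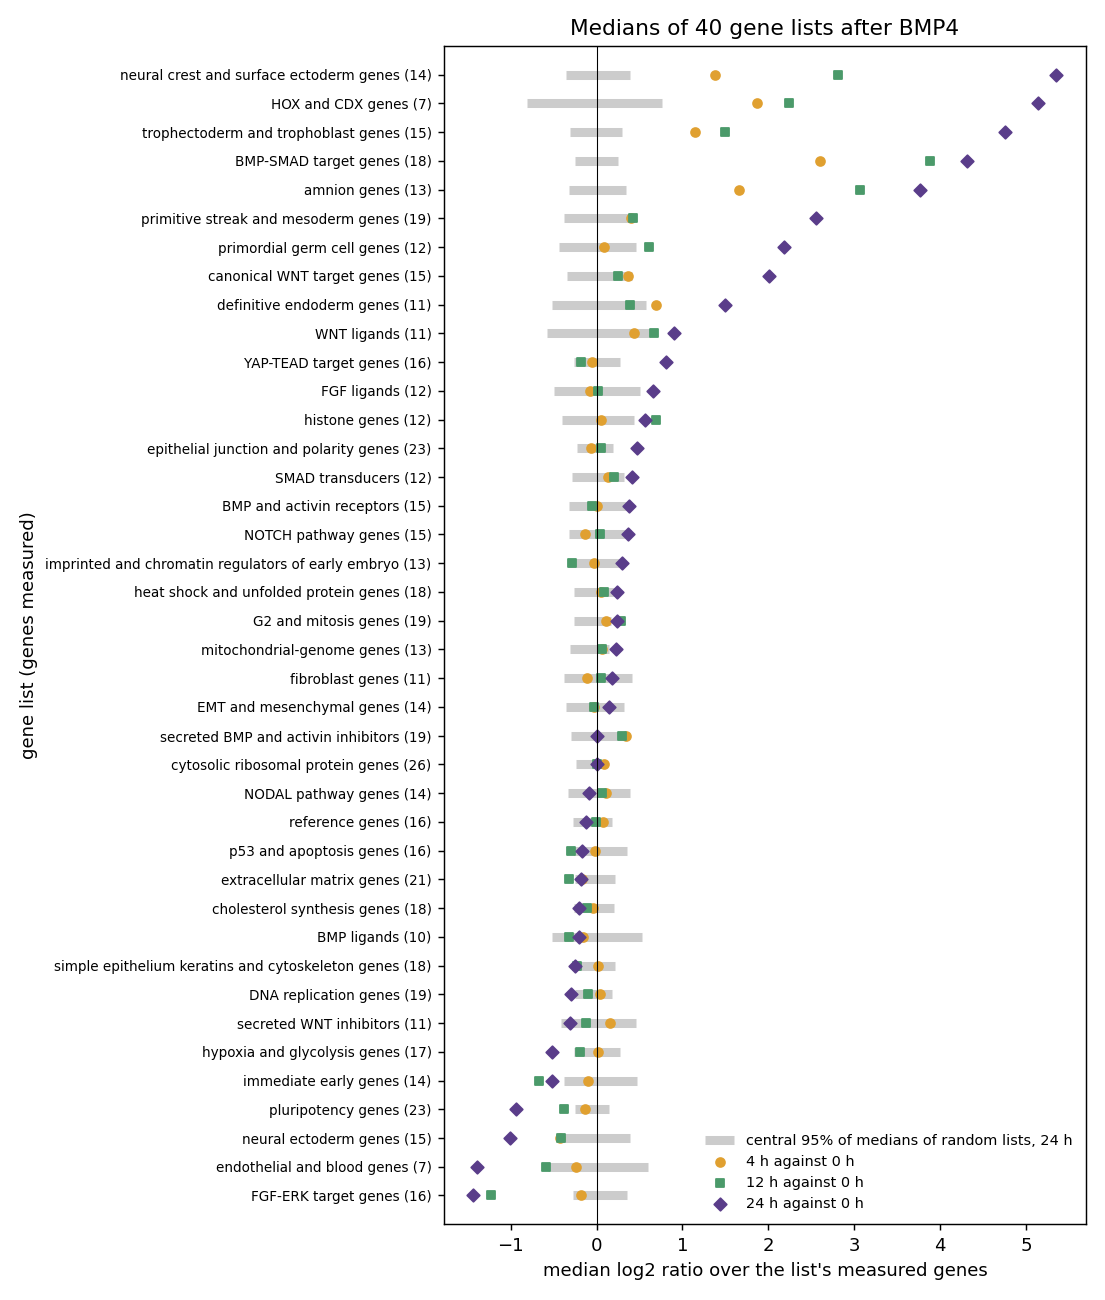
Median log2 ratio (horizontal axis) of each of the 40 gene lists (vertical axis, with the number of genes measured) at 4 h (circles), 12 h (squares) and 24 h (diamonds) against 0 h, 1 library per time, with grey bars for the central 95% of the medians of 10000 random lists at 24 h. Neural crest and surface ectoderm genes (5.35) stood highest and FGF-ERK target genes (-1.43) lowest at 24 h.

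By the largest ratios at 24 h, the higher genes included LINC02593, SLC6A4, GATA3-AS1, TFAP2A, TNFSF8, CDX2, ERP27 and CD48. SLC6A4, the serotonin transporter gene, had 0 reads at 0 h and was at least 133-fold higher, ERP27 at least 83.0-fold and CD48 at least 74.9-fold. TNFSF8 went from 2.01 to 1586 counts (interval 141 to 31156). The lower genes with symbols were TLR4, SPATA31C1, SORBS2, D21S2088E, HTR1A, FOXD3 and IL20RA, with 3 identifiers without symbols. TLR4, a receptor gene of innate immunity, had 161 counts at 0 h and 0 reads at 24 h, at least 28.1-fold lower, and SORBS2 was 62.0-fold lower (45.1 to 90.5).

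Between successive times, 791 genes were at least 2-fold higher and 582 lower at 12 h than at 4 h, and 1104 higher and 1118 lower at 24 h than at 12 h. Of the 494 genes higher at 4 h, 407 were also higher at 12 h and 339 at 24 h, 320 at both, 68 at neither, and 27 were at least 2-fold lower than 0 h at 24 h. Of the 200 lower at 4 h, 87 were also lower at 12 h and 86 at 24 h, 70 at both, 97 at neither, and 39 were higher at 24 h. Independent lists of these sizes would share 32.9 and 57.3 higher genes and 9.40 and 21.0 lower genes with 12 and 24 h. Unchanged libraries simulated with counting noise alone gave 8 higher genes at 4 h, 1 and 2 of them shared with 12 and 24 h, and 7 lower, 0 and 0 shared. All comparisons use the same 0 h library, so part of the excess may come from it.

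Of 4999 genes whose highest value was at least 2 times the lowest, 1458 were highest at 0 h, 698 at 4 h, 672 at 12 h and 2171 at 24 h. Genes at least 2-fold above every other time numbered 70 at 0 h, 33 at 4 h, 43 at 12 h and 903 at 24 h, and genes at least 2-fold below every other time 320, 50, 42 and 807. GREM1, WNT3 and ID3 were highest at 4 h, NOG and ID1 at 12 h, and FST, NODAL, BAMBI, BMPR2 and CDX2 at 24 h.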

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

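Protein-coding genes only, intervals that exclude 1, and intervals with each read as 1 count were alternatives chosen after the data were seen. The balance of higher against lower genes turned in some settings. At 24 h against 0 h it turned with upper-quartile scaling, to 1749 higher and 2160 lower. That scaling multiplies each library by 1 factor, so it lowered the ratios at 24 h by about the same amount for all genes. Why the upper quartiles of the libraries differed was not tested. At 4 h against 0 h it turned with no minimum. At 24 h against 12 h, where the counts were near equal, higher genes led with a pseudocount of 10 (1068 and 1011), a minimum mean of 200 (776 and 697), no minimum, 4-fold, protein-coding genes only (933 and 874) and both interval rules beyond 2-fold (813 and 537 by read pairs, 879 and 678 by reads). Pseudocounts, total-count, upper-quartile and TMM scaling, centring, protein-coding genes only and intervals that exclude 1 moved no count by more than 1.5-fold. Leaving out a library was not possible with 1 library per time. No paired analysis was possible because each time had 1 library. Upper-quartile scaling moved the median of all genes at 24 h against 0 h by more than 0.1, to -0.11.

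The counts that moved did so because the alternative admits more or fewer genes. With a minimum mean of 10, the higher and lower genes against 0 h were 968 and 750 at 4 h, 1979 and 1504 at 12 h, and the lower at 24 h 2780. They were 1612 and 1143 at 12 h against 4 h and 1775 and 1857 at 24 h against 12 h, and 2286, 1310 and 1411 genes were highest at 0, 4 and 12 h. With a minimum mean of 200, they were 317 and 77 at 4 h, 769 and 535 at 12 h, 485 and 348 at 12 h against 4 h, and 697 lower at 24 h against 12 h, with 430 and 371 genes highest at 4 and 12 h. With no minimum, they were 3652 and 3880 at 4 h, 4879 and 4491 at 12 h, 6204 and 5960 at 24 h, 4646 and 3859 at 12 h against 4 h, and 4635 and 4584 at 24 h against 12 h. Genes highest at 0, 4, 12 and 24 h then numbered 5219, 4034, 3618 and 6182.

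At 1.5-fold, the higher and lower genes against 0 h were 1050 and 728 at 4 h, 2233 and 1850 at 12 h, and 3432 and 3142 at 24 h. They were 1901 and 1514 at 12 h against 4 h and 2129 and 2334 at 24 h against 12 h, and the genes highest at each time 2357, 1374, 1358 and 3557. At 4-fold, they were 159 and 21 at 4 h, 383 and 153 at 12 h, 809 and 605 at 24 h, 162 and 85 at 12 h against 4 h, and 369 and 190 at 24 h against 12 h, with 519, 204, 144 and 850 genes highest at each time. With the 95% interval wholly beyond 2-fold, they were 269 and 58 at 4 h, 697 and 496 at 12 h, 377 and 275 at 12 h against 4 h, and 537 lower at 24 h against 12 h. The same with each read as 1 count gave 309 and 74 at 4 h, 457 and 349 at 12 h against 4 h, and 678 lower at 24 h against 12 h.

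Of 1080 list medians under the alternatives, 38 turned sign, none of them of a list and time outside the central 95% of random lists. With a minimum mean of 200, which leaves fewer genes, the BMP ligand median turned to 0.04 at 4 h, 2.10 at 12 h and 1.85 at 24 h, and the NODAL pathway median at 24 h turned to 0.21 there and with a minimum mean of 10 or none. The other turns were of medians near 0. Outside the binomial interval of the median lay 6 values. These were ribosomal protein genes with total-count scaling (0.03 at 12 h, -0.04 at 24 h) and upper-quartile scaling (-0.06 and -0.12), and with upper-quartile scaling G2 and mitosis genes at 12 h (0.23) and cholesterol genes at 24 h (-0.33). Setting values under the floor to the floor is not among the 1080. It did turn the median of a list outside the central 95%: WNT ligands at 12 h, at percentile 99.7, went from 0.67 to -0.06.

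Of 3222 named gene values under the alternatives, 101 left their counting interval. Upper-quartile scaling gave 68 of them, with log2 shifts up to 0.13, total-count scaling 15, up to 0.04, and centring 2, of 0.01. The other 16 were with a pseudocount of 10, by 1.95 to 3.31, and are genes with few or no reads at 1 of the times. Named gene values past 2-fold dropped under it in 19 cases. With a pseudocount of 10 these were FOSB, GABRA4, MUC15, TBXT, VGLL1 and WNT6 at 4 h and DNMT3L, KRT23 and WNT6 at 12 h. With total-count scaling they were FURIN at 4 h and CDH2 and FAS at 12 h. With upper-quartile scaling they were FST, H1-2, HES1, TEAD1 and TP53INP1 at 12 h and BMPR1A and SC5D at 24 h.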

Other observations

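The genes in this paragraph and the next were chosen after their values were seen. Several genes had their highest value at 24 h. WLS, which encodes the carrier that WNT ligands need for secretion, had 354, 335, 2977 and 136727 normalized counts at 0, 4, 12 and 24 h. The hypoxia-inducible factor gene EPAS1 had 991, 895, 420 and 22686, and PPARG, a nuclear receptor gene with a part in trophoblast, 11.1, 23.6, 48.6 and 2364. ALDH1A2, which encodes an enzyme that makes retinoic acid, had 12.1, 11.8, 42 and 1823, and the HOX cofactor gene MEIS1 32.2, 25.8, 40.1 and 2109.

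Other genes had their highest or lowest value at 4 or 12 h. WT1 had 254 counts at 4 h and 6.04, 45.8 and 28.7 at the other times, and LMX1B 531 at 4 h against 111, 141 and 111. PKDCC, which encodes a secreted kinase, had 9868, 10767, 1631 and 26675 counts, lowest at 12 h. IRX2 was lowest at 4 h, with 4278, 815, 4008 and 7994 counts.

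The tests in the rest of this part were all chosen after the results were seen. The non-coding RNAs GATA3-AS1, GATA2-AS1 and LINC02593, picked after their values were seen, were higher after BMP4 together with a neighbouring gene. If a fixed share of the neighbour's reads fell on the RNA, the share would be level, but for GATA3-AS1 it went from 0.92% of the GATA3 reads at 4 h to 3.64% at 24 h, 3.88-fold (2.62 to 5.97) when reads are rounded up to whole read pairs, and for GATA2-AS1 it went up 2.41-fold (1.98 to 2.95). From 0 to 4 h the share of GATA2-AS1 was level, at 4.82% and 4.75%. For LINC02593 the ratio of 24 h to 4 h was 1.07 (0.949 to 1.20), and at 0 h the share was 2.22%, from 1 read. These are single libraries with intervals of counting error, so a fixed share stays open for all 3 RNAs, and libraries that mark strand would tell.

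FGF-ERK target genes were lower at 12 h in cultures whose medium was prepared with basic FGF. These data do not show how much FGF was present at 12 h. The choice among the scalings tried does not account for the lower target genes, as their median stayed at -1.19 or below under each of 4 others. The median of all genes at 12 h ranged only from -0.05 with upper-quartile to 0.04 with total-count scaling. A larger error of scaling was therefore not tested. Replacement of cells by ones that express neither group would lower pluripotency genes alike, and 19 of 23 had counting intervals wholly above the FGF-ERK median, but with 1 library this stays open. A fault of the 12 h culture alone would not lower the list at 24 h, where the median was -1.43, but that too is 1 library against the same 0 h library, so handling stays open. Replicate cultures would tell.

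Even read numbers outnumbered odd ones among genes with few reads. The lowest even share was 74.9% (lower bound 74.1%), which would follow if both mates of a read pair were counted. A step taken at the wrong size would leave no odd numbers, and the odd share was 23.1% or more. The counting options used would settle it.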
